A study of Mus musculus with 4 samples.

How the data were processed

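The series holds RNA sequencing of the right ventricle of 4 adult mouse hearts, 2 Ezh2-deficient and 2 wild type, grouped by their sample titles. Per the labels' protocols, libraries were built from polyadenylated RNA, denatured, partly re-annealed and digested with a duplex-specific nuclease, so that reads of abundant transcripts are under-represented relative to their RNA. Levels of different genes within a library are therefore not proportional to RNA, and a fold change of an abundant gene may be compressed. Per the submitters' processing notes, TopHat 1.2.0 and Cufflinks were used with the mouse build mm9. The counting rule, the use of strand, the annotation and any filter on rows are not given in the sources used here.

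The deposited table gives, per the file headers, a whole-number read count per gene row and library, which the authors did not normalise and which was the input here. It also gives the authors' normalised value, which equals CPM (reads of the row over all reads of the library in the table, scaled to the usual CPM total), the authors' ratio of each pair of libraries, and the authors' p-value for each pair, a comparison of single libraries whose test is not given in the sources used here. The ratios and p-values were only counted, and the authors' CPM was checked against the counts and not otherwise used. The table has 29595 rows, of which 7646 had no read in any library. It holds 381 spans shared by 2 or more rows (779 rows), so a gene can be counted under more than 1 name. Row names are gene symbols or accessions as deposited; Xist was found through its transcript accession in the RefSeq gene table of a later assembly, used for names only. Start positions are counted from 0 in the table, as 13 of 13 mitochondrial genes showed against an annotation, and are printed here counted from 1, on mm9.

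Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, after filterByExpr with the group (16128 rows kept) and TMM scaling, with all 4 libraries, no covariate and Benjamini-Hochberg adjustment. All tests are two-sided. An adjusted p under 0.05 counts as a call. Levels are TMM-scaled CPM, given as mean ± SD with n = 2, and the SE of a log2 fold change was taken from the quasi-likelihood F statistic. Nothing in the labels names a litter, day or batch. The design text speaks of 2 hearts of each kind. The p-values of these gene tests measure the spread between these hearts. With 2 against 2 there are 3 ways to split the libraries, so no test by relabelling can give a p under 1 in 3.

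In total, 31 gene lists, with 615 genes, were fixed before the data were examined, as were the tests, most alternatives and the rule for the genes named in the text. The rule took 12 genes chosen in advance (among them Ezh2, Nppa, Nppb, Acta1, Myh7, Col1a1, Postn, Isl1, Cdkn2a and Pax6) and, per direction, up to 8 called genes of the largest change with both mutants on the same side of both wild types and a mean of at least 1 CPM. Some genes that the rule names, and 1 of the lists, are not reported here. The rule also took, per list, called members up to 6 or otherwise the 2 of smallest p, and the 4 genes of smallest p in each direction. Outside the choices per list, clone-type names, genes on X or Y and immune receptor segments were counted, not named. Sex-linked genes, D230007K08Rik and rows kept out of the test by the filter are named outside the rule, and other genes outside it are marked where they appear. Lists with at least 5 tested members (25 lists) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, adjusted over the 25 lists. Camera sets the genes of a list against all other genes under that assumed correlation. Its p-values at the preset correlation therefore do not measure the spread between hearts. With the correlation estimated from the data, and with fry, 0 of the 7 called lists kept their call. The smallest adjusted p were 0.378 and 0.0580. Fry tests whether the genes of a list move one way, without comparing them with other genes. With 2 libraries per group, camera with an estimated correlation has few degrees of freedom and can rarely pass. A list not called there may lack power, and no list call is upheld by it.

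Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters and thresholds, leaving out each library in turn, and leaving out sex-linked rows together with rows above 1% of a library (1115 rows). A library left alone in its group was assumed to vary like the other group. Results without a library therefore rest on a single heart in 1 group. A list call kept there does not measure the spread between hearts. After the data were seen, 4 kinds were added: 1 row per locus, a correction of GC content and transcript length by a loess surface, the same rows without that correction, and the hypertrophy list without Nppa, Nppb and Myl4. Transcripts came from the annotation of a later mouse assembly, and 81.4% of tested rows matched 1 by name.

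The test was tried on simulated counts with the means, library sizes and dispersions of the 16128 rows and 200 genes changed by known folds. It recovered 26.9% of genes changed 2-fold, 86.6% of those changed 4-fold and 98.5% of those changed 8-fold, and 19 of 160 calls were unchanged genes, a larger share than the threshold allows. A planted list of 20 genes raised 1.5-fold had a camera p of 8.87e-06 and a list of unchanged genes 0.0754. Genes were drawn independently and with the same dispersion in both groups, so these lists do not test the preset correlation. The depth of 18177642 to 23853394 reads per library means that 3 reads, the floor for a count of 0, correspond to 0.126 to 0.165 CPM. Counting intervals (95%, exact binomial) and floors cover counting error only. The libraries of a group were separate: a chi-square of their counts over rows with at least 20 reads was 32.4 per degree of freedom for the mutants and 64.5 for the wild types.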

Results

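RNA was measured in the right ventricle of 4 adult mouse hearts on a mixed C57BL/6 background, 2 from animals deficient in Ezh2 and 2 from wild-type animals. Ezh2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which marks genes for repression by methylating histones. The hearts are named here mutant 1, mutant 3, wild type 1 and wild type 2, with the numbers of the labels. The libraries came from polyadenylated RNA and were treated with a duplex-specific nuclease, an enzyme that digests re-annealed double-stranded DNA and so lowers the share of abundant transcripts before sequencing. The comparison of the groups asks which transcripts of the adult ventricle differ when Ezh2 is lacking. The table held 21707784, 23853394, 20093783 and 18177642 reads for mutant 1, mutant 3, wild type 1 and wild type 2. Mitochondrially encoded genes took 40.3% (95% Clopper-Pearson interval 40.3 to 40.3) and 47.3% (47.3 to 47.4) of the reads of the mutants. In the wild types they took 34.7% (34.7 to 34.7) and 41.2% (41.1 to 41.2) of the reads.

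Y-linked transcripts were abundant in the mutant hearts and nearly absent from the wild-type hearts. Ddx3y had 754 and 659 reads in the mutants and 2 and 2 in the wild types. Eif2s3y had 466 and 430 reads in the mutants and 1 and 1 in the wild types, a ratio of 461 with a 95% counting interval of 127 to 3812. The X-inactivation transcript Xist (row NR_001463) had 64 and 17 reads in the mutants and 638 and 3227 in the wild types. Sex therefore followed genotype in these 4 libraries, so no difference reported here can be assigned to genotype apart from sex. The mutant libraries were also more alike than the wild-type libraries. Pearson's r of log2 CPM was taken across 16128 genes, which are not independent replicates. It was 0.982 between the mutants, 0.947 between the wild types and 0.946 to 0.957 between a mutant and a wild type. With mutant 1 and mutant 3 it was 0.947 and 0.946 for wild type 1 and 0.955 and 0.957 for wild type 2. Wild type 2 was thus closer to both mutants than to wild type 1.

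Ezh2 itself was read at a similar level in both groups. The row for Ezh2 (chromosome 6, 47480280 to 47545337) had 73 and 70 reads in the mutants and 77 and 67 in the wild types, or 3.48 ± 0.101 CPM (SD, n = 2) in the mutants and 3.40 ± 0.0409 in the wild types. The log2 fold change of 0.03 ± 0.30 (SE) had an adjusted p of 0.978. The labels do not state which part of the gene was deleted or in which cells, and reads from a remaining part or from other cells count alike, so this row does not check the labels. All directions below rest on the labels. The other PRC2 subunits and partners did not pass the test either. Here 0 of 9 tested members did over all genes, 0 when adjusted over the list alone and 0 by DESeq2, with 0 higher and 1 lower at an unadjusted p under 0.05. That member was Jarid2, which helps to recruit the complex, at 17.99 ± 2.74 against 26.8 ± 5.05 CPM (adjusted p = 0.451). Phf1 came next at 25.9 ± 1.28 against 19.4 ± 0.962 CPM (adjusted p = 0.533). The list as a whole was not called (camera adjusted p = 0.715 over 25 lists).

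Outside the Y chromosome, the genes that rose in the mutants included genes of cardiac stress and sarcomere structure. Ankrd1, a stretch-responsive cofactor of the sarcomere and nucleus (chromosome 19, 36186455 to 36194334), was 8.23 times as high in the mutants, at 2562 ± 182 CPM (SD, n = 2) in the mutants and 311 ± 5.13 in the wild types (log2 fold change 3.04 ± 0.27 SE, adjusted p = 0.00920). Nppa, the gene of atrial natriuretic peptide (chromosome 4, 147374855 to 147376176), was 11.5 times as high, at 3142 ± 241 CPM (SD, n = 2) in the mutants and 274 ± 143 in the wild types (3.52 ± 0.41, adjusted p = 0.0316). Myot, which encodes the Z-disc protein myotilin (chromosome 18, 44493728 to 44515376), was 7.32 times as high, at 64.7 ± 2.08 against 8.82 ± 2.58 CPM (2.87 ± 0.27, adjusted p = 0.0124). Cdkn2a, a cell cycle inhibitor locus long known as a Polycomb target (chromosome 4, 88920377 to 88940523), was close to silent in the wild types. It had 70 and 48 reads in the mutants and 3 and 1 in the wild types, a ratio of 30.3 with a 95% counting interval of 11.5 to 113 (adjusted p = 0.0463).

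Of the other genes that rose, Dio2 encodes the deiodinase that activates thyroid hormone (chromosome 12, 91962992 to 91976878). It stood at 7.06 ± 0.238 against 1.14 ± 0.165 CPM (log2 fold change 2.63 ± 0.32, adjusted p = 0.0378). Nrn1, which encodes the membrane-anchored protein neuritin (chromosome 13, 36817495 to 36826323), stood at 21.1 ± 1.1005 against 3.99 ± 0.591 CPM (2.40 ± 0.25, adjusted p = 0.0171). Cpxm2, a carboxypeptidase-like gene (chromosome 7, 139234499 to 139346422), stood at 23.9 ± 7.33 against 3.68 ± 1.29 CPM (2.69 ± 0.34, adjusted p = 0.0463). Nlrc3, of the NOD-like receptor family (chromosome 16, 3946933 to 3976632), stood at 7.67 ± 1.03 against 0.831 ± 0.105 CPM (3.20 ± 0.34, adjusted p = 0.0171). A second row over the same span, D230007K08Rik, held nearly the same reads (178, 134, 16 and 15 in mutant 1, mutant 3, wild type 1 and wild type 2) and counts as a further call.

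The 4 genes that fell included Pdk4, the kinase that restrains entry of pyruvate into mitochondrial oxidation (chromosome 6, 5433351 to 5446278). It was at 108 ± 12.1 CPM (SD, n = 2) in the mutants and 373 ± 35.6 in the wild types (log2 fold change -1.78 ± 0.23, adjusted p = 0.0463). Baiap2l1, an actin-binding adaptor (chromosome 5, 145025394 to 145118981), showed the lowest ratio, with 14.6 ± 0.894 against 70.6 ± 10.9 CPM (-2.27 ± 0.23, adjusted p = 0.0156). Lrtm1 (chromosome 14, 29831440 to 29842962) was at 59.8 ± 0.0990 against 209 ± 6.10 CPM (-1.81 ± 0.21, adjusted p = 0.0299). Lrrc15 (chromosome 16, 30269390 to 30283311) was at 7.70 ± 0.0632 against 26.2 ± 3.05 CPM (-1.77 ± 0.23, adjusted p = 0.0463). Both encode leucine-rich repeat membrane proteins. Lrtm1 lies over Cacna2d3, Baiap2l1 over Bri3, and Cpxm2 and Dio2 over a further row each. No source used here states that strand was used in counting, so reads of these overlapping pairs can be split or shared between rows. The same holds for Timp1 over Syn1, Prg4 over Tpr, Ddit3 over Mars and Alx4 over Ext2, named further on.

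**Figure D1:**
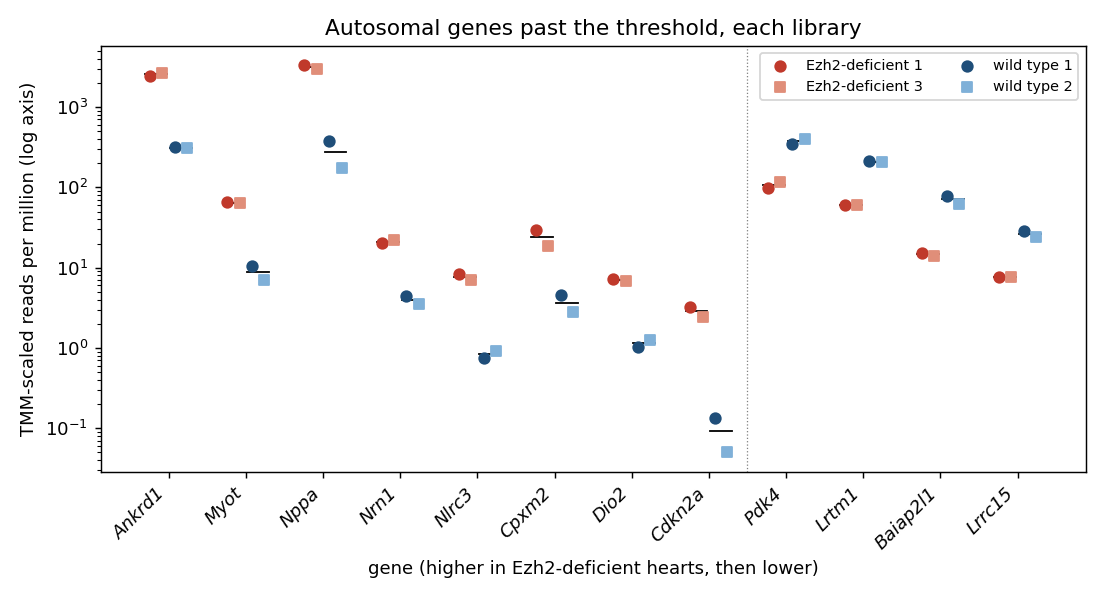
TMM-scaled CPM (log axis) of 12 autosomal genes past the threshold, with a point for each of the 4 libraries and short lines at the group means. Ankrd1 stood at 2562 against 311 CPM and Pdk4 at 108 against 373.

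In all, 21 of 16128 tested rows passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 17 higher and 4 lower in the mutants. Of these, 8 were rows on the Y chromosome and 13 were autosomal (9 higher, 4 lower), while 1752 rows had an unadjusted p under 0.05 (1046 higher, 706 lower). The Y-linked rows repeat some genes: Ddx3y and dby share a span, as Jarid1d and Smcy do in part. Jarid1d had 155 and 125 reads in the mutants and 0 and 0 in the wild types. Set against a floor of 3 reads over the wild-type group it was 96.0-fold higher, with a 95% lower counting limit of 77.6. Uty had 130 and 109 reads in the mutants and 4 and 0 in the wild types. Of the fixed sex-linked list, 4 of 4 tested members passed over all genes, also when adjusted over the list alone.

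The count of calls varied with the test and with single libraries. DESeq2 called 203 genes (158 higher, 45 lower), including all 21. Without mutant 1 the count was 63, without mutant 3 it was 109, without wild type 1 it was 2046 and without wild type 2 it was 3675. Scaling by total counts alone moved the median log2 fold change of all genes by -0.29 and gave 76 higher and 80 lower calls, so all directions are relative to the TMM scaling. Without mutant 1, Pdk4 (adjusted p = 0.0988, range over its alternatives 1.64e-09 to 0.101) and Lrrc15 (0.0701, range 5.83e-06 to 0.0952) no longer passed. Over 15 alternatives of test, scaling, filter and libraries, Ankrd1, Myot and Baiap2l1 were called in all, Nrn1 and Lrtm1 in 14, Nppa and Nlrc3 in 13, Dio2 in 10, Cpxm2 and Pdk4 in 8 and Lrrc15 in 7. Cdkn2a was called in 8 of 14. Only Ankrd1, Myot and Baiap2l1 were called without sex-linked and abundant rows. In the authors' deposited table of library-against-library ratios, 75 rows were at least 2-fold higher and 113 at least 2-fold lower with a p under 0.001 in all 4 comparisons of a mutant with a wild type. By the same fold and p in either direction, the wild types differed from each other in 1808 of 29595 rows and the mutants in 408.

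Genes of the hypertrophy and fetal programme were mostly higher in the mutant ventricles. Of 18 tested members, 2 passed over all genes (Ankrd1 and Nppa), 14 passed when adjusted over the list alone, all of them higher, and 8 passed by DESeq2. Nppb, the gene of B-type natriuretic peptide, was at 363 ± 82.7 CPM (SD, n = 2) in the mutants and 88.7 ± 46.5 in the wild types (log2 fold change 2.03 ± 0.38 SE, adjusted p = 0.136). The skeletal actin gene Acta1 was at 1472 ± 257 against 266 ± 212 CPM (2.47 ± 0.54, adjusted p = 0.175). Chosen after their values were seen, Gdf15, a stress-induced cytokine gene, had 193 and 48 reads in the mutants and 7 and 8 in the wild types. The X-linked LIM-domain gene Fhl1, chosen likewise, was at 147 ± 0.163 against 71.2 ± 3.02 CPM. Myh7, the slow myosin heavy chain of the fetal programme, did not pass, at 5268 ± 981 against 4488 ± 511 CPM (adjusted p = 0.816). The median log2 fold change of the list was 1.09 (camera adjusted p = 2.82e-13 over 25 lists; adjusted p = 0.378 with an estimated correlation). The natriuretic peptide genes also differed between the wild types: Nppa had 8432 and 3437 reads there.

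Skeletal muscle contractile genes were higher as a list, with a different makeup in each mutant. Of 23 tested members, 1 passed over all genes (Myot), 14 passed adjusted over the list alone, all higher, and 6 passed by DESeq2. The members named next, except Acta1 and Myot, were chosen after their values were seen. In both mutants, the slow troponin genes Tnnt1 and Tnni1, the fast myosin gene Myh4 and the light chain gene Myl1 exceeded both wild types. Tnnt1 had 1815 and 869 reads in the mutants and 299 and 226 in the wild types, Tnni1 had 70, 45, 1 and 4 in the same order, Myh4 had 951, 655, 224 and 238, and Myl1 had 422, 1212, 163 and 132. All 4 passed over the list alone, not over all genes. Myh4 shares sequence with the other myosin heavy chain genes. In mutant 1 alone, fast-fibre genes stood far above the other 3 libraries. Tnnt3 had 1516 and 20 reads in the mutants and 8 and 5 in the wild types, Mylpf had 798, 11, 19 and 4, Tnni2 had 682, 5, 21 and 18 and the fast calcium pump gene Atp2a1 had 848, 28, 19 and 32. The median log2 fold change was 2.32, and 0.56 without mutant 1. The camera adjusted p of the list was 1.55e-07 over 25 lists and 0.533 with an estimated correlation. The myogenic regulatory factors, Myod1 and its relatives, had 7, 5, 5 and 3 reads in all in mutant 1, mutant 3, wild type 1 and wild type 2, and none was tested.

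**Figure D2:**
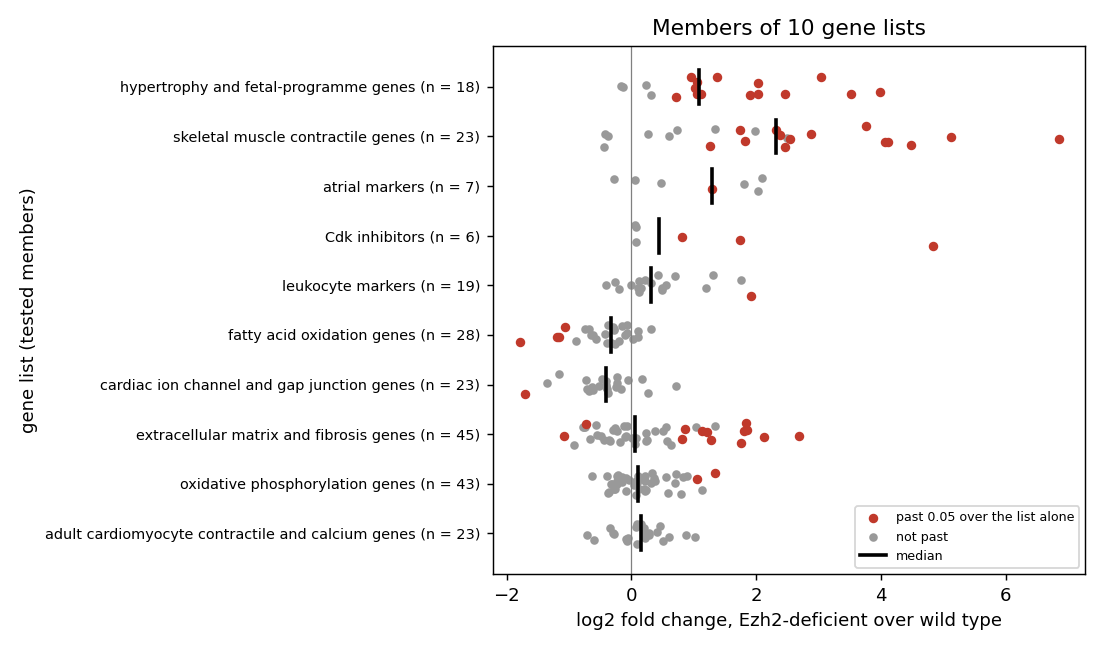
Log2 fold changes (horizontal axis, mutant over wild type) of the tested members of 10 gene lists. Each point is a gene, red where it passes 0.05 adjusted over its list alone, and the black bar is the median of the list, 1.09 for the hypertrophy and fetal-programme genes and -0.32 for the fatty acid oxidation genes.

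**Figure D3:**
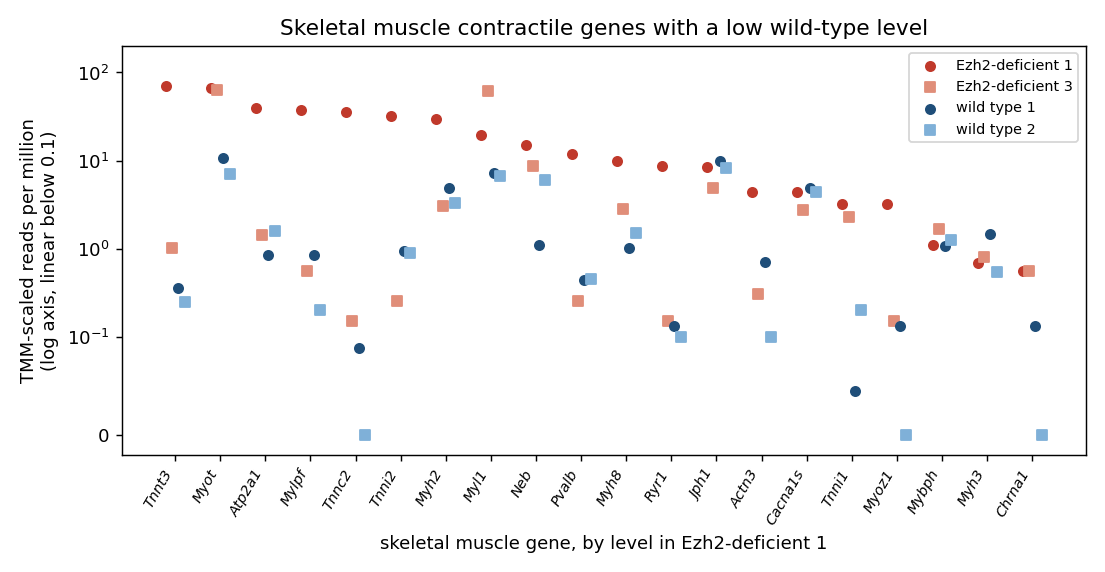
TMM-scaled CPM (log axis, linear below 0.1) of 20 skeletal muscle contractile genes with a wild-type mean under 10 CPM, in each library. Tnnt3 stands at 70.7 CPM in mutant 1 and 1.01 in mutant 3, while Myot and Myl1 are high in both mutants.

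Genes that inhibit the cyclin-dependent kinases were higher in the mutants as a list at the preset correlation, but not in all members. Cdkn1b, Cdkn1c and Cdkn2c, named after their values were seen, changed little, with log2 fold changes of 0.08, 0.07 and 0.06. Of 6 Cdk inhibitors tested, Cdkn2a passed over all genes and 3 passed adjusted over the list alone, Cdkn2a, Cdkn1a and Cdkn2b, all higher. The last 2 were named after their values were seen, with Cdkn1a at 24.8 ± 3.11 against 14.1 ± 2.63 CPM and Cdkn2b, the neighbour of Cdkn2a, at 34, 16, 7 and 8 reads in mutant 1, mutant 3, wild type 1 and wild type 2. That list was called (camera adjusted p = 0.0281 over 25 lists; adjusted p = 0.533 with an estimated correlation), but not without mutant 1 (adjusted p = 0.0573), mutant 3 (0.0562), wild type 1 (0.0619) or wild type 2 (0.189; range over its alternatives 0.0117 to 0.533). Its median was 0.45, and 0.68 without wild type 1; 1 of the 6 passed by DESeq2.

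Developmental regulators were mostly too low to test. Of 39 Hox genes, 2 were tested and 0 passed by edgeR over all genes, over the list alone or by DESeq2, with 0 at an unadjusted p under 0.05. Hoxb3 was at 1.22 ± 0.278 against 0.778 ± 0.0331 CPM and Hoxb2 at 0.910 ± 0.363 against 0.666 ± 0.444 CPM. Of 77 listed non-cardiac regulators, 9 were tested. None passed by edgeR over all genes or by DESeq2, with 1 higher and 0 lower at an unadjusted p under 0.05, and 1 passed over the list alone, the homeobox gene Alx4 with 42 and 35 reads in the mutants and 8 and 8 in the wild types. Gata3 was at 7, 11, 16 and 24 reads in the same order. Irx1, Irx2, Irx3, Irx5 and Irx6 were also among the 9, with Irx3 at 33.2 ± 0.0767 against 36.8 ± 6.34 CPM. The tests of this list therefore say little on members near silent in the wild types. Pax6, the eye and brain regulator, had 0, 0, 0 and 4 reads, which is not enough to show a difference. Of 19 tested cardiac progenitor and developmental regulators, 0 passed over all genes, over the list alone or by DESeq2, with 1 higher and 0 lower at an unadjusted p under 0.05. Gata6 was at 24.4 ± 6.76 against 36.1 ± 0.804 CPM. Isl1, a marker of the second heart field, had 4 and 8 reads in the mutants and 0 and 0 in the wild types. Set against a floor of 3 reads over the group it was 4.12-fold higher, with a 95% lower counting limit of 2.86. It was too low to be tested by edgeR and did not pass by DESeq2 (adjusted p = 0.634). Neither list was called (camera adjusted p = 0.708 and 0.931); the cardiac list's median of -0.07 and mean of 0.12 differ in sign, and its test direction, down, turned to up with the GC and length correction.

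Genes of fatty acid oxidation were mostly lower in the mutants, and the list was called at the preset correlation only. Of 28 tested members, 24 had a log2 fold change below 0, 1 passed over all genes (Pdk4), 4 passed adjusted over the list alone, all lower, and 3 passed by DESeq2. Among the 4 were, named after their values were seen, the mitochondrial carrier gene Ucp3 at 31.2 ± 3.53 against 71.1 ± 3.36 CPM and the acyl-CoA thioesterase gene Acot1 at 7.48 ± 1.33 against 16.7 ± 0.00765 CPM. The median was -0.32 (camera adjusted p = 1.55e-07 over 25 lists, and 0.378 with an estimated correlation). Cardiac ion channel and gap junction genes were mostly lower as well, with 20 of 23 below 0 and a median of -0.41. The camera adjusted p was 1.82e-05 over 25 lists and 0.378 with an estimated correlation. With the GC and length correction the median was -0.17, and the list was still called. None passed over all genes, with 0 higher and 5 lower at an unadjusted p under 0.05, 1 passed over the list alone and 2 passed by DESeq2. The potassium channel gene Kcnd2 was at 3.80 ± 0.430 against 12.5 ± 4.15 CPM (log2 fold change -1.71 ± 0.32), and the channel subunit gene Kcne1 was at 10.5 ± 5.67 against 26.6 ± 3.83 CPM. Both lists were compared between hearts of different sex, as all were.

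Other energy and contractile genes went both ways. Of 43 oxidative phosphorylation genes, 0 passed over all genes by edgeR, with 9 higher and 1 lower at an unadjusted p under 0.05, 2 passed adjusted over the list alone and 3 passed by DESeq2. The 2 were Ndufb3, at 203 ± 5.38 against 80.03 ± 2.29 CPM, and Ndufa4, at 1322 ± 60.2 against 637 ± 7.93 CPM. The list was not called (camera adjusted p = 0.134 over 25 lists), but was without wild type 1 (adjusted p = 2.32e-06; range over its alternatives 2.32e-06 to 0.902). Its test direction, up, turned to down with the GC and length correction. Of 18 glycolysis genes, 0 passed by edgeR over all genes or over the list alone, 0 by DESeq2 and 0 at an unadjusted p under 0.05. The glucose transporter gene Slc2a4 was at 353 ± 16.4 against 482 ± 41.9 CPM and Pfkp at 49.6 ± 8.90 against 35.7 ± 5.80 CPM (camera adjusted p = 0.979 over 25 lists, median -0.04, test direction up, down by total-count scaling; without wild type 1 adjusted p = 0.0133, range over its alternatives 0.0133 to 0.995). Of 23 adult contractile and calcium-handling genes, 0 passed by edgeR over all genes or over the list alone, 2 passed by DESeq2, and 3 higher and 2 lower had an unadjusted p under 0.05. The slow troponin C gene Tnnc1 was at 3136 ± 36.0 against 1542 ± 357 CPM and the ventricular light chain gene Myl2 at 17703 ± 1069 against 9653 ± 1722 CPM (camera adjusted p = 0.369 over 25 lists; without wild type 1 adjusted p = 0.0427, range over its alternatives 0.0427 to 0.865).

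Extracellular matrix genes moved in opposite directions within 1 list. Of 45 tested, 0 passed over all genes by edgeR, with 12 higher and 7 lower at an unadjusted p under 0.05, 13 passed adjusted over the list alone (11 higher, 2 lower) and 8 passed by DESeq2 (7 higher, 1 lower). The matricellular gene Postn was at 72.3 ± 11.7 CPM (SD, n = 2) in the mutants and 20.8 ± 9.31 in the wild types (log2 fold change 1.80 ± 0.33 SE, adjusted p = 0.125). Timp1, an X-linked gene of an inhibitor of matrix proteases, was at 17.5 ± 5.06 against 3.99 ± 1.16 CPM. The latent TGF-beta binding protein gene Ltbp2 was at 19.4 ± 1.68 against 2.99 ± 1.88 CPM. The fibrillar collagen gene Col1a1 was at 107 ± 23.2 against 146 ± 43.4 CPM (log2 fold change -0.45 ± 0.28, adjusted p = 0.601). The 2 members lower over the list alone, named after their values were seen, were the collagen genes Col6a3, at 28.0 ± 7.69 against 58.8 ± 7.63 CPM, and Col5a1, at 40.5 ± 4.58 against 67.2 ± 1.22 CPM. The list was not called (camera adjusted p = 0.252 over 25 lists, median 0.07), but was with the GC and length correction (adjusted p = 0.0106, median 0.21), without mutant 1 (0.0158) and without wild type 1 (0.0133; range over its alternatives 0.0106 to 0.998).

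Markers of other cell types in the ventricle were compared in the same way. Of 12 fibroblast markers, 0 passed over all genes, 2 passed over the list alone and by DESeq2, both higher, and 3 higher and 0 lower had an unadjusted p under 0.05. They were Dpep1, at 18.4 ± 4.04 against 7.32 ± 1.17 CPM, and S100a4, at 34.1 ± 12.0 against 13.6 ± 5.28 CPM. The list was not called (camera adjusted p = 0.252 over 25 lists; without wild type 1 adjusted p = 0.00727, range over its alternatives 0.00727 to 0.998). Of 14 smooth muscle and pericyte markers, 0 passed by either count or by DESeq2, with 0 higher and 3 lower at an unadjusted p under 0.05. Smooth muscle actin gene Acta2 was at 67.6 ± 1.46 against 114 ± 32.0 CPM and Notch3 at 32.2 ± 0.481 against 46.5 ± 2.57 CPM (camera adjusted p = 0.918 over 25 lists; median 0.07 and mean 0.06, test direction down, up with the GC and length correction). Of 17 endothelial markers, 0 passed by either count or by DESeq2, with 3 higher and 0 lower at an unadjusted p under 0.05. Egfl7 was at 68.2 ± 1.497 against 42.4 ± 1.41 CPM and Ly6c1 at 77.3 ± 8.59 against 49.8 ± 6.73 CPM (camera adjusted p = 0.750 over 25 lists; median -0.05, mean 0.11, test direction up, down by total-count scaling).

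At the preset correlation, leukocyte and atrial markers were higher in the mutants as lists. Of 19 leukocyte markers, 0 passed over all genes by edgeR, with 4 higher and 0 lower at an unadjusted p under 0.05, and 1 passed over the list alone and by DESeq2, the galectin gene Lgals3, expressed in macrophages, with 153 and 86 reads in the mutants and 43 and 22 in the wild types. The neutrophil gene S100a9 had 46, 68, 23 and 12 in the same order. Other members went both ways. Emr1 and Csf1r had log2 fold changes of -0.41 and -0.19, and Cd68, Ptprc and Cd163 of 0.13, 0.32 and 0.70. Numbers of leukocytes were not measured. The list was called (camera adjusted p = 0.0368 over 25 lists; adjusted p = 0.731 with an estimated correlation), but not with the GC and length correction (adjusted p = 0.0643) or without mutant 1 (0.158) or wild type 2 (0.845; range over its alternatives 0.0133 to 0.845). Its median was 0.32, 0.52 without wild type 1 and 0.14 without wild type 2. Of 7 atrial markers, 0 passed over all genes or by DESeq2, 3 higher and 0 lower had an unadjusted p under 0.05, and Dkk3 passed over the list alone, at 13.7 ± 0.567 against 5.58 ± 2.56 CPM. The atrial light chain gene Myl4 had 1150 and 862 reads in the mutants and 475 and 51 in the wild types, and Myl7, named after its values were seen, had 1658, 1218, 665 and 54 in the same order, so the wild types differed from each other in both. The list, which shares Myl4 with the hypertrophy list, was called (camera adjusted p = 0.00517 over 25 lists, and 0.533 with an estimated correlation).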

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

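The tests of the skeletal muscle and hypertrophy patterns below were chosen after the result was seen; those of the wild-type pair were written before it. Listed genes that the filter kept out of the test, but that reached 10 reads in a mutant library while no wild-type library had more than 3, are given first, with reads in mutant 1, mutant 3, wild type 1 and wild type 2. Skeletal muscle genes made up 4 of the 9. The fast troponin C gene Tnnc2 had 759, 3, 2 and 0, the calcium release channel gene Ryr1 had 188, 3, 3 and 2, the Z-disc gene Myoz1 had 69, 3, 3 and 0 and the acetylcholine receptor gene Chrna1 had 12, 11, 3 and 0. Of the developmental genes, Hoxd3 had 10, 5, 0 and 3 (over 1700109F18Rik) and Otx2 had 11, 3, 1 and 0. The brown fat gene Ucp1 had 19, 0, 0 and 0. The cartilage genes Acan and Lect1 had 1, 14, 1 and 0 and 20, 11, 0 and 3.

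Fast skeletal muscle transcripts stood out in mutant 1: Tnnt3 was 69.8 times (95% counting interval 45.004 to 115) and Tnnc2 233 times (79.4 to 1132) as high as in mutant 3. An effect of Ezh2 deficiency alike in both mutant hearts would not by itself give a difference between them. The ratios below describe that difference and are no independent test, since it prompted them. Over 20 listed genes with a wild-type mean under 10 CPM and at least 10 reads in a mutant library, the median log2 ratio of mutant 1 to mutant 3 was 2.48, while random sets matched on level lay between -0.17 and 0.16 (95% of 10000 sets). Without these filters, over 30 listed genes with a read, it was 0.80 (random sets -0.13 to 0.13). The ratio of mutant 3 to the wild types was 1.03 (95% counting interval 0.452 to 2.19) for Mylpf and 1.18 (95% counting interval 0.716 to 1.90) for Atp2a1, but 3.30 (95% counting interval 1.56 to 7.22) for Tnnt3. Some skeletal muscle carried into the sample of mutant 1 stays open. It would raise fast-fibre genes in that library. Of the 20, 11 were over 3 times as high there as in mutant 3 and as in the wild-type mean. That fell short of the share set for it after the result was seen. The 20 also hold the slow gene Tnni1 and genes already read in the wild types. Of these, Jph1, named after its values were seen, stood at 9.84 and 8.25 CPM there. The shortfall therefore cannot decide on carried-over muscle. Among the 11 were Tnnt3, Atp2a1, Mylpf, Tnnc2 and Tnni2, whereas Myl1 was higher in mutant 3 and Myot was close in both. Of the 31 listed genes found in the table, 23 were read deeply enough in these hearts to be tested. A response of the heart that differs between animals was not tested, as each mutant is a single animal.

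The hypertrophy list rose by a median of 1.09 on the log2 scale. A bias from GC content or transcript length is argued against as its whole cause, since the median was 1.09 after correction (adjusted p = 4.10e-14). Atrial tissue in the mutant samples stays open. The members other than Nppa, Nppb and Myl4 had a median of 1.05 (camera adjusted p = 1.22e-09, and 0.296 with an estimated correlation, where the full list is not called either). That would argue against atrial tissue only if these members are not high in atrium, which was not measured. In wild type 1 and wild type 2, Myl7 had 665 and 54 reads. Acta1 differed in the same direction, with 9344 and 2316, while Ankrd1, with 7073 and 6116, and Fhl1, with 1646 and 1372, were close. The log2 fold change of Nppa exceeded that of the atrial gene Myl7 by 1.42 with a combined SE of 0.915, which leaves atrial tissue open for Nppa too. Genotype and sex cannot be told apart here, as 0 of the 4 libraries came from a heart of the sex of the other group.

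The wild-type libraries were less alike than the mutants: the SD of the log2 ratio of the pair was 0.716 against 0.395 over 13127 rows with a transcript. Counting noise of low rows is argued against, since among 3489 rows with a mean of at least 500 reads the wild-type SD was 2.46 times that of the mutants. Part of the difference went with GC content and length, and whether they account for all of it stays open. The log2 ratio of wild type 1 to wild type 2 had a Pearson's r of 0.521 with GC content across genes (-0.00571 for mutant 1 to mutant 3). Correction took off 33.1% of the variance of the wild-type ratio and 1.09% of that of the mutant ratio. It left the wild-type SD at 1.49 times that of the mutants. No biological explanation was tested, since the design gives none for a difference within the wild types.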

How the results depend on the processing

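The alternatives by locus, by GC content and length, and without Nppa, Nppb and Myl4 were chosen after seeing the data. The main count was 21 (17 higher, 4 lower). It was 156 (76, 80) by total counts, 317 (249, 68) without a filter, 13 (11, 2) with a mean of at least 50 counts, 203 (158, 45) by DESeq2, 69 (56, 13) at an adjusted p of 0.10, 3 (2, 1) without sex-linked rows and rows above 1%, and 69 (53, 16) with the GC and length correction, against 14 (12, 2) on the same rows without it. Limma-voom gave 14 (11, 3), DESeq2 size factors 16 (14, 2), upper-quartile factors 15 (13, 2) and 1 row per locus 15 (13, 2). Without 1 library it ranged from 63 to 3675, higher calls from 55 to 2200 and lower calls from 8 to 1475. Fewer adjusted tests, and the loss of the sex-linked and most abundant rows, are part of the construction of some of these; otherwise the cause was not tested. Of the 13 autosomal calls, 13 were also called by DESeq2, without a filter, by total counts, with the correction and without mutant 3, wild type 1 or wild type 2. Fewer were called without mutant 1 (11), without the correction on rows with a transcript (9), with DESeq2 size factors (8), upper-quartile factors (8), 1 row per locus (8), a mean of at least 50 counts (7), limma-voom (7) and without sex-linked and abundant rows (3). Ankrd1, Myot and Baiap2l1 passed in all 15 settings of test, scaling, filter and libraries. With a fold of at least 2 the count stayed 21.

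Ezh2, not called in any setting, turned to -0.26 by total counts, -0.00104 without sex-linked and abundant rows and -0.0323 with the correction. By total counts Myh7 turned to -0.0700 and Cidea to -0.14. Without 1 library in turn, log2 fold changes ran over 0, from -0.12 to 1.35 for Hoxb2, -0.0967 to 0.48 for Cidea (both turned without wild type 2) and -1.80 to 5.14 for Tnni2 (turned without mutant 1). None of these was called in the main test or in the alternative. Over 102 other genes, 1185 of 1502 values kept direction and side of the threshold, 270 newly passed 42 no longer passed and 5 turned.

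Of the lists, 7 were called, 0 with an estimated correlation, 0 by fry, 7 with DESeq2 size factors, 8 by total counts, 7 with the correction (6 of the same lists, with leukocyte markers lost and extracellular matrix gained), and 5 to 13 without 1 library. Over 25 lists, 173 of 226 values kept direction and side, 21 lost a call, 9 gained 1 and 23 turned. The direction of the test turned for lists not called in the main test, with these medians. By total counts these were -0.34 for endothelial, -0.33 for glycolysis and -0.19 for neural genes, and by fry -0.0664 for cardiac progenitor genes. With the correction they were -0.0818 for oxidative phosphorylation, 0.30 for smooth muscle, 0.12 for neural and 0.0628 for cardiac progenitor genes. Without 1 library in turn medians ran from -0.0388 to 0.21 for smooth muscle, 0.0764 to 0.60 for non-cardiac regulators, -0.16 to 0.14 for endothelial, -0.23 to 0.23 for glycolysis, 0.0166 to 0.39 for immediate early, -0.12 to 0.44 for neural and -0.0753 to 0.23 for other PRC2 genes. They ran from -0.0649 to 0.18 for cardiac progenitor, -0.00597 to 0.36 for fibroblast, -0.0696 to 0.37 for oxidative phosphorylation and -0.26 to 0.31 for circadian genes. Pearson's r between the mutants was 0.982 and Spearman's rho 0.985. No paired analysis was possible because only the number 1 occurs in both groups. With 2 libraries a group, recovery of 2-fold changes in simulated counts was 26.9%, so depth and replicates leave most changes of that size undetected.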

Other observations

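Marker lists of tissues and states not described above gave few differences. The articular gene Prg4, on the list of valve and cartilage markers, was 3.01 times as high in the mutants, at 37.8 ± 2.86 CPM (SD, n = 2) in the mutants and 12.6 ± 0.687 in the wild types (log2 fold change 1.59 ± 0.22 SE, adjusted p = 0.0638). It and Chad, with 26 and 79 reads in the mutants and 21 and 4 in the wild types, passed adjusted over the list alone, and Prg4 passed by DESeq2. With 3 tested members the list was too short for a list test. The epicardial marker Upk3b was lower over its list alone, with 37 and 35 reads in the mutants and 79 and 104 in the wild types, and Upk1b had 10, 6, 21 and 22 in the same order (camera adjusted p = 0.251 over 25 lists). Neural crest receptor gene Ngfr was lower over its list alone, with 14, 13, 40 and 48, and S100b had 33, 20, 9 and 1 (camera adjusted p = 0.931 over 25 lists; median 0.11, mean 0.17, test direction down, up with the GC and length correction). Of 4 erythroid genes tested, 0 passed by edgeR over all genes, over the list alone or by DESeq2, with 2 higher at an unadjusted p under 0.05. The globin genes Hba-a2, at 1975 ± 629 against 1173 ± 271 CPM, and Hbb-b1, at 816 ± 133 against 498 ± 73.3 CPM, share reads with near-identical copies. Of 2 adipocyte genes tested, 0 passed by the same counts or at an unadjusted p under 0.05, with Cfd at 80, 64, 48 and 3 reads and Cidea at 603, 720, 773 and 461.

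Clock, stress and proliferation genes showed single members only. Of 14 circadian clock genes, Per1, at 20.03 ± 2.43 against 44.6 ± 14.8 CPM, and Hlf, at 14.5 ± 0.899 against 27.2 ± 3.71 CPM, were lower over the list alone. By edgeR 0 passed over all genes, with 0 higher and 2 lower at an unadjusted p under 0.05, and Per1 passed by DESeq2 (camera adjusted p = 0.708 over 25 lists; without wild type 1 adjusted p = 0.0465, range over its alternatives 0.0465 to 0.894). Of 13 heat shock and unfolded protein genes, Hspb1, a small heat shock protein gene, at 253 ± 1.39 against 91.9 ± 40.9 CPM, and Ddit3, at 15.1 ± 1.00 against 7.94 ± 1.09 CPM, were higher and Hspa5, named after its values were seen, was lower over the list alone, at 152 ± 2.51 against 249.8 ± 9.43 CPM. None passed over all genes by edgeR, with 3 higher and 1 lower at an unadjusted p under 0.05, and 1 passed by DESeq2 (camera adjusted p = 0.252 over 25 lists). Of 21 cell cycle genes, 0 passed by edgeR over all genes, over the list alone or by DESeq2, with 1 at an unadjusted p under 0.05 in each direction. Top2a was at 2.79 ± 0.0766 against 5.86 ± 1.61 CPM and Ccnd2 at 150.3 ± 10.6 against 103 ± 1.03 CPM (camera adjusted p = 0.715 over 25 lists). By the same counts 0 of 14 interferon-response genes passed, with 2 higher at an unadjusted p under 0.05. Bst2 was at 27.7 ± 4.90 against 15.7 ± 3.72 CPM and Ifit3 at 7.81 ± 1.29 against 4.48 ± 1.35 CPM (camera adjusted p = 0.327 over 25 lists). Of 18 immediate early genes 0 passed likewise, with 2 higher and 1 lower at an unadjusted p under 0.05. Ier2 was at 13.95 ± 1.78 against 8.12 ± 1.30 CPM and Atf3 at 2.69 ± 0.502 against 5.21 ± 0.884 CPM (camera adjusted p = 0.369 over 25 lists).

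The row AK019083, chosen after its values were seen, lies on chromosome 19 (5798395 to 5802671). It had 134699 and 128657 reads in the mutants and 26673 and 105301 in the wild types, so wild type 1 stood apart from the other 3 libraries.

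A hypothesis written before its test was that Ezh2-deficient hearts read more genes that are near silent in the wild type than the other way round. With reads thinned to equal TMM-scaled depth over 28360 autosomal rows, 8 rows went from at most 1 read in both wild types to at least 10 in both mutants, and 1 (Oprd1) went the other way. The other 2 of the 3 splits of the libraries gave 0 and 1 in 1 case and 1 and 0 in the other. The 8, named after their values were seen, were Ccl8, Tchhl1, BC094642, Cyp1a1, Gsta2chr9-, mitsugumin29, Brunol4 and Clca2. Tchhl1 had 45 and 37 reads in the mutants and 0 and 0 in the wild types, and Cyp1a1 had 19 and 22 against 0 and 0. None of the 8 is on the Hox or other developmental lists, and 0 of the 6 that were tested passed the threshold. The 8 rows go with a loss of repression in Ezh2-deficient hearts, as a hypothesis. Gsta2chr9+, a second Gsta2 row, had 47 and 26 reads in the mutants and 1 and 2 in the wild types. Mitsugumin29 is another name of Sypl2, whose own row had 53 and 33 reads in the mutants and 4 and 2 in the wild types. BC094642 had 2 reads in wild type 1 before thinning. Not every row of the 8 therefore stands for a gene silent in the wild types. Before thinning, 20203 and 20540 rows held reads in the mutants and 18638 and 19027 in the wild types. Whether this wider difference in detection accounts for the 8 was not tested. The 3 splits are too few for a share under 0.05, the highest other count being 1, and sex of the hearts stays open as a cause, since it follows genotype.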
